A study of Pinus tabuliformis with 21 samples.

How the data were processed

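Messenger RNA was isolated with poly(A) beads from foliage of Pinus tabuliformis, and libraries were sequenced as read pairs of 150 bp per end on an Illumina HiSeq 2500, per the labels' protocols. Reads were trimmed with Trimmomatic 0.36, per the labels' protocols, and counted with featureCounts 1.5.3, per the submitters' processing notes. The aligner, the reference sequence, its annotation, the use of strand and the treatment of reads with several matches are not given in the sources used here. The authors deposited the result as raw counts per gene model, without normalization: 84525 gene models in 21 libraries, with whole numbers whose totals differ between libraries. Of these gene models, 45122 had 0 counts in every library and 39403 had at least 1. Conifer genomes hold many near-identical gene copies, and counting may divide or drop reads among them, so single gene models stand under that uncertainty.

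Groups were taken from the sample labels: a control at 0 h and UV-B or UV-C for 1, 3 or 7 d, with 3 libraries each. The treatment protocol describes 180 seedlings in groups of 20, including 4 h groups of both bands, which are not analysed here. The labels number the replicates in each group without saying what a number stands for.

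The main test was edgeR 4.0.16 (quasi-likelihood fit and F-test, two-sided) under R 4.3.3 on the deposited counts, fitted to all 21 libraries with 1 mean per group, TMM normalization and the filterByExpr filter, which left 18265 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. Each treatment was compared with the control, UV-C with UV-B at each duration, and 7 d with 1 d within each band, which makes 11 comparisons, and the difference of the last pair was tested as an interaction. Genes common to the bands were called in the same direction under both, and genes distinctive of a band were called under that band, not under the other, and in the direct contrast of the bands. Standard errors of log2 fold changes were the fold change divided by the square root of the F statistic. Levels in CPM, counts scaled to a common library size, use TMM-scaled library sizes, and correlations of libraries use log2-CPM with a prior count of 2.

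Where a group held 0 counts of a gene, its fold change was replaced by the bound that 3 counts over the group allow in medians and in counts of 8-fold changes. Where a followed gene had 1 to 3 counts in a group, the ratio of levels is given with an exact (Clopper-Pearson) 95% interval of the counts, which covers counting error only. With 6177212 to 8560163 counts per library, 1 CPM corresponds to fewer than 10 counts, so low genes are measured coarsely.

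Because the table pairs no identifier with a name, the genes to follow were chosen by a rule fixed before the data were examined, among genes with a mean of at least 2 log2-CPM. It takes the gene called in the same direction in all 6 comparisons with the control whose smallest absolute log2 fold change is largest, once among risers and once among fallers. It takes likewise the gene called higher, and the gene called lower, in UV-C than UV-B at all 3 durations. The 25 gene lists fixed beforehand (among them flavonoid synthesis, DNA repair, photosynthesis, markers of other cell types and signs of RNA quality) could not be matched to identifiers without names, so no list was tested.

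Comparisons that share control libraries were set beside 20 simulated data sets with unchanged groups, drawn with each group's own dispersion. In these, the 11 comparisons gave between 0.05 and 3.95 false calls on average, except 14.8 for UV-C against UV-B at 3 d. With so few calls, overlaps of the simulated lists are near 0 by construction. They do not measure what shared controls add among many called genes. The fit was also tested on simulated data with genes changed by known folds among 18265. For UV-B at 1 d against the control it recovered 40 of 66 4-fold, 14 of 67 2-fold and 3 of 67 1.5-fold changes, with 3 false calls. For UV-C at 3 d against UV-B at 3 d it recovered 44 of 66, 17 of 67 and 5 of 67, with 46 false calls. For UV-C at 3 d against the control there were 31 false calls beside 88, 38 and 13 recovered. For UV-C at 1 d against UV-B at 1 d it recovered 38 of 66, 17 of 67 and 0 of 67, with 14 false calls. In these contrasts of UV-C, false calls were a larger share of all calls than the threshold allows. For UV-C at 7 d against UV-B at 7 d there were 0 false calls. No pair of replicates agreed within sampling noise (chi-square per degree of freedom from 3.82 to 60.17), so no library was taken for a repeat deposit of another. This does not tell separate seedlings from repeat preparations.

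The alternatives fixed beforehand were DESeq2 size factors and upper quartile factors in place of TMM, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, a fit of only the groups compared, a minimum log2 fold change of 1, the replicate number as a block, and leaving out each library in turn. After the spread was seen to differ between groups, limma 3.58.1 (voom) with a quality weight per group was added.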

Results

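Foliage of the Chinese pine Pinus tabuliformis, a conifer of northern China, was profiled by poly(A) RNA sequencing after ultraviolet light had been added to the greenhouse lamps. Seedlings aged 2.5 years received UV-B (280 to 320 nm, peak at 306 nm, 280 µW/cm2) or UV-C (230 to 270 nm, peak at 254 nm, 28 µW/cm2) for 1, 3 or 7 d. Control seedlings received neither band and were sampled at 0 h. UV-B reaches the ground in sunlight and is perceived by plants, whereas UV-C is absorbed in the atmosphere and reaches plants from lamps. The series asks which responses the bands have in common and which are distinctive of either. The data comprised 21 libraries in 7 groups of 3. The bands were given at different intensities, so each contrast of UV-C with UV-B compares the treatments as given. The control was sampled at 0 h only, so a contrast with it spans the time of the experiment as well as the irradiation. Contrasts of the bands at equal duration do not. Contrasts of 7 d with 1 d also span time, with no unirradiated library at either.

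Counts assigned to gene models ranged from 6177212 to 8560163 per library. Control libraries held between 7455114 and 8065146 counts and detected 23968 ± 78 gene models (SD, n = 3), and the group means of the irradiated libraries lay between 24394 and 25096 gene models. In the 11 comparisons the mean total of the first group was between 8.1% below (UV-B at 1 d against the control) and 6.6% above (UV-C against UV-B at 1 d) that of the second. An exact two-sided permutation test of 3 libraries against 3 cannot give a p below 0.1, so it decides nothing on whether totals differ (smallest p of 11 comparisons 0.2, Benjamini-Hochberg adjusted p = 0.63). Control replicates lay closest together, with a biological coefficient of variation of 13.8%. Among irradiated groups it ran from 19.7% in UV-C at 7 d to 41.3% in UV-C at 3 d. UV-C 3 d replicate 3 stood apart from its mates: over genes, which are not independent replicates, its mean correlation with them was 0.902, against 0.96 between replicates 1 and 2. The labels do not say whether replicates came from separate seedlings, so the p-values measure only the spread between these samples, which may be technical.

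**Figure D1:**
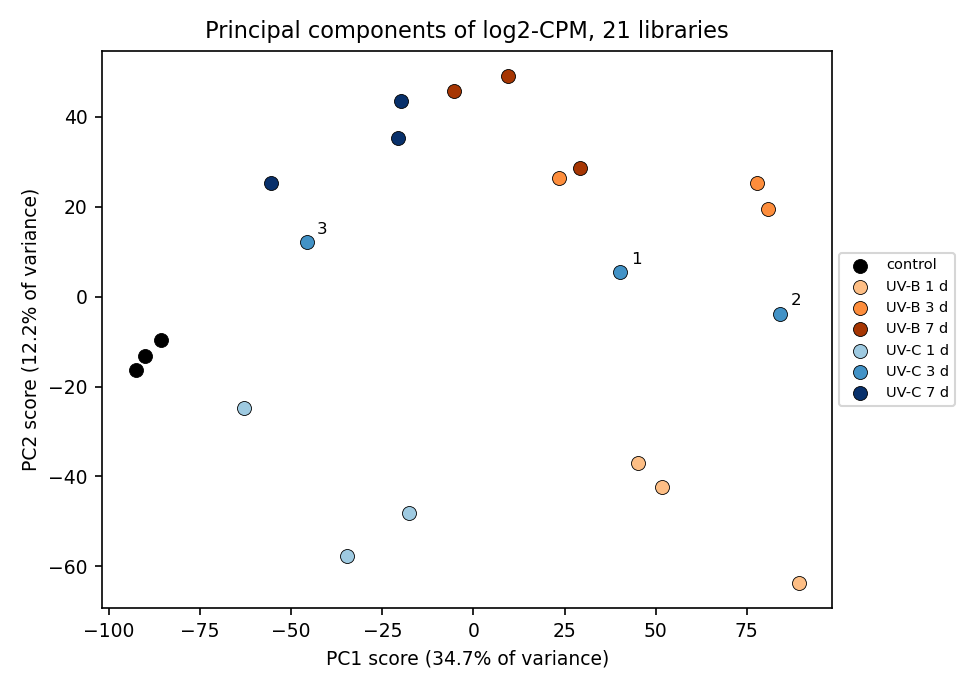
Principal components of log2-CPM (counts scaled to a common library size) over 18265 tested genes, with each point 1 library, colour for the group and numbers for the replicates of UV-C at 3 d. The first component carried 34.7% of the variance: control libraries lay between -92.7 and -85.8, UV-B 1 d libraries between 45 and 89.3, and UV-C 3 d replicates 1, 2 and 3 at 40.3, 84.2 and -45.8.

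The count table pairs no gene model with a gene name, so groups of genes are described by their behaviour, and 4 gene models chosen by a fixed rule are followed by identifier. Of 18265 genes tested, 10231 were called against the control under at least 1 of the 6 treatments and 8034 under none. All calls come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05.

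A large part of the tested transcripts differed from the control after 1 d of UV-B. At 1 d, 3758 genes were higher than in the control and 3160 were lower, together 37.9% of the genes tested. The genes that rose moved further, with a median log2 fold change of 1.67, than those that fell, with a median of -0.83. A rise of at least 8-fold was reached by 932 genes and a fall of that size by 116. Of the 932 strong risers, 710 averaged under 1 CPM in the control, which choosing genes by a high ratio to the control favours. No control library held a count for 188 of the risers, and placing those at the lower bound that 3 counts over the group allow left the median at 1.67. The counts of strong risers use that bound throughout.

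Fewer genes differed from the control at the longer UV-B durations. At 3 d, 3205 genes were higher and 2750 lower, with medians of 1.68 and -0.84, although upper quartile scaling gave 2957 and 3009. At 7 d, 1835 were higher and 1530 lower, with medians of 1.63 and -0.77. Strong risers numbered 882 at 3 d and 463 at 7 d. Of the 3758 genes that rose at 1 d, 2323 were also called higher at 3 d and 1277 at 7 d, where independent lists would share 659 and 378. Of the 3160 that fell, 1993 were also lower at 3 d and 1172 at 7 d, where independent lists would share 476 and 265. Simulated unchanged groups set against the same controls shared at most 1 call in each of these overlaps, but had few calls to share. The 3 controls cannot be divided into sets of 2, so part of the excess may come from the shared controls. The 7 d count of 3365 fell to 2154 without control replicate 1 and to 1933 without control replicate 2, and rose to 5060 in limma voom with a quality weight per group (group weights below), an alternative chosen after seeing the data that changes the test as well as the weights.

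At all 3 durations of UV-B, 1194 genes were above the control and 1074 below it. Independent lists, which leave out the shared controls, would hold 66.2 and 39.9. Simulated unchanged groups held 0, with few calls to share. The 1194 persistent risers took 3.01% ± 0.13 of all counts in the control (SD, n = 3), 9.05% ± 1.1 at 1 d of UV-B, 9.32% ± 1.7 at 3 d and 6.84% ± 0.91 at 7 d. In the UV-C groups the same genes took 4.73% ± 0.63 at 1 d, 7.49% ± 2 at 3 d and 4.73% ± 0.52 at 7 d. Contrasts of UV-C were not used to choose them, but its libraries entered the filter, the scaling and the estimate of spread. The 1074 persistent fallers took 12.5% ± 0.25 in the control and 6.56% ± 0.3, 6.99% ± 0.29 and 7.36% ± 0.23 after 1, 3 and 7 d of UV-B. Under UV-C they took 10.5% ± 0.66, 9.17% ± 1.1 and 9.23% ± 0.26. The control libraries enter both the choice of these genes and the shares set beside them. The count of 2268 persistent genes was 1442 without control replicate 1 and 1317 without control replicate 2. Fallers outnumbered risers with group weights (1646 and 1320), in a fit of the groups compared alone (1336 and 1306), and without control replicate 2 (682 and 635) or 3 (835 and 822), so neither direction clearly prevailed.

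In the main fit, the fewest genes were called against the control at 1 d of UV-C and the most at 3 d. Fits of only the groups compared and group weights put 7 d above 3 d. At 1 d, 676 genes were higher than in the control and 409 lower, 5.9% of those tested. At 3 d, 2777 were higher and 1931 lower, 25.8% of those tested, and at 7 d 1162 were higher and 1121 lower, 12.5%. Median log2 fold changes of the risers were 1.82, 1.64 and 1.18 at 1, 3 and 7 d, and 1.81, 1.64 and 1.18 with genes absent from the control at their bound. The fallers had medians of -0.87, -0.82 and -0.78. Rises of at least 8-fold were reached by 161, 785 and 229 genes. Of the 785 strong risers at 3 d, 608 averaged under 1 CPM in the control.

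Genes called at 1 d of UV-C were largely called again at 3 d. Of 676 risers, 483 were also higher at 3 d and 274 at 7 d, where independent lists would share 103 and 43. Of 409 fallers, 268 were also lower at 3 d and 182 at 7 d, where independent lists would share 43 and 25. Simulated unchanged groups shared at most 1 call, and the shared controls may account for part of the excess. At all 3 durations of UV-C, 241 genes were above the control and 151 below it, against 6.54 and 2.65 for independent lists. Simulated unchanged groups gave 0, with few calls to share. The 241 took 0.51% ± 0.018 of counts in the control, and 1.29% ± 0.2, 1.72% ± 0.53 and 1.07% ± 0.14 at 1, 3 and 7 d of UV-C. In UV-B libraries the same genes took 1.98% ± 0.3, 1.8% ± 0.35 and 1.33% ± 0.24.

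The UV-C counts depended on the libraries used and on the fit. Leaving out a library leaves 2 in its group, which lowers power. Similar drops for each replicate of a group therefore do not single out a library, here and below. The 1 d count of 1085 was 303, 220 and 300 without control replicates 1, 2 and 3, 333 and 355 without UV-C 1 d replicates 1 and 2, 1966 with DESeq2, and 1873, of which 977 were higher, with group weights. The 3 d count of 4708 was 3008 and 2886 without control replicates 1 and 2, 2168 without UV-C 3 d replicate 2, 5858 without UV-C 3 d replicate 3, and 2711 in a fit of these 6 libraries alone. The 7 d count of 2283 was 1094, 965 and 1394 without control replicates 1, 2 and 3, and 1041 and 1366 without UV-C 7 d replicates 1 and 3. It rose to 4194 in a fit of its own groups and to 4353 with group weights, above the 3774 of UV-C at 3 d in that fit, so the order of 3 d and 7 d differed between fits. At 7 d fallers outnumbered risers with upper quartile scaling (1151 and 1088), a filter of 1 CPM in 3 libraries (1123 and 1109) and group weights (2209 and 2144), and without control replicate 1 (579 and 515), 2 (539 and 426) or 3 (752 and 642). The persistent count of 392 was 129, 81 and 139 without control replicates 1, 2 and 3, 183 and 162 without UV-C 1 d replicates 1 and 2, and 214 and 258 without UV-C 7 d replicates 1 and 3. With group weights it was 637, of which 261 rose and 376 fell, in place of 241 and 151.

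**Figure D2:**
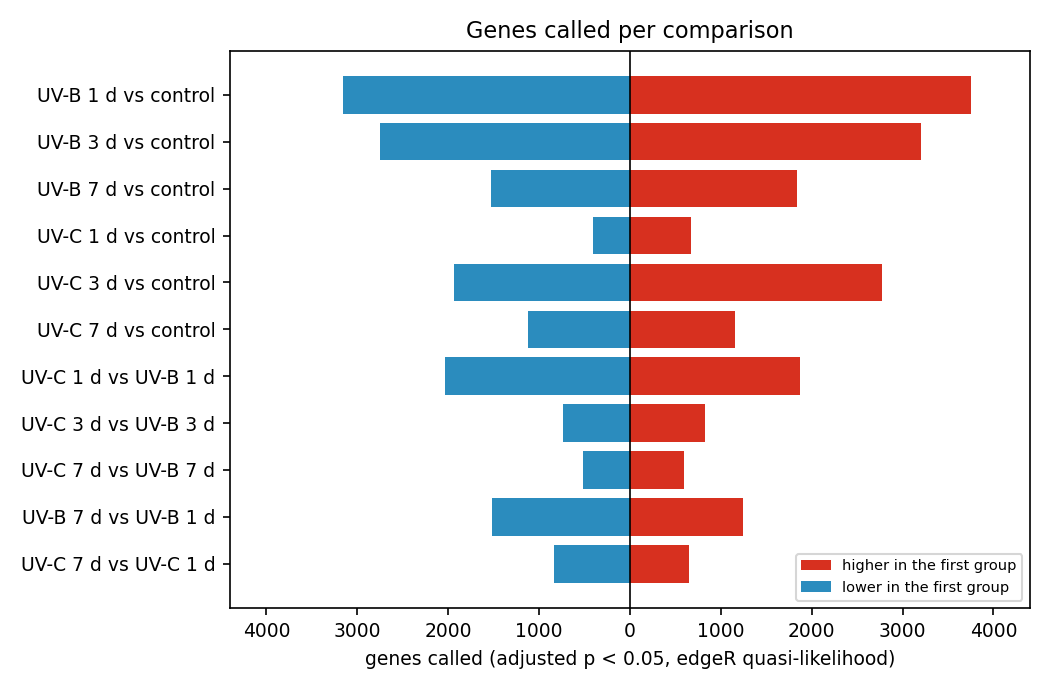
Genes called higher (red, to the right) and lower (blue, to the left) in the first group named, at an adjusted p under 0.05 in each of 11 comparisons, counted over 18265 tested genes with 3 libraries per group. UV-B at 1 d has the longest bars, with 3758 higher and 3160 lower, and UV-C at 1 d has the shortest of the 6 comparisons with the control, with 676 and 409.

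At every duration, genes were called against the control in the same direction under both bands. The control was taken at 0 h, so a change with time alone would give the same pattern, here and in the correlations below. At 1 d, 526 genes rose under both bands and 283 fell under both, at 3 d 1964 rose and 1129 fell, and at 7 d 677 rose and 600 fell. Independent lists would share 139 and 71 genes at 1 d, 487 and 291 at 3 d, and 117 and 94 at 7 d. Simulated unchanged groups shared at most 1, with few calls to share, so neither measures what the shared controls add. Opposite directions were called for 11 of the 820 genes called in both bands at 1 d, 37 of 3130 at 3 d and 16 of 1293 at 7 d. Of the strong risers, 113 at 1 d, 596 at 3 d and 166 at 7 d rose at least 8-fold under both bands, an overlap that the shared controls favour.

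Fold changes of the bands against the control were correlated over all tested genes. Pearson's r over genes was 0.68 at 1 d, 0.84 at 3 d and 0.75 at 7 d, and Spearman's rho was 0.61, 0.71 and 0.63. Genes are not independent replicates, and shared controls alone gave r of 0.37, 0.35 and 0.43 in simulated unchanged groups. The covariance was 1.17, 2.04 and 1.16 against 0.1 in the simulation, a difference of 1.07, 1.94 and 1.06. The direction was the same for 72.2%, 76.5% and 72.5% of genes, against 60%, 59.5% and 63% in the simulation. Genes with 0 counts in all control libraries were drawn as 0 in every simulated group, so they showed no change there. In the data, 207 risers of UV-B at 3 d were of this kind. The differences from the simulation may therefore still hold a part from the shared controls.

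The size of the common set moved with the libraries used. At 1 d the count of 809 was 242, 182 and 244 without control replicates 1, 2 and 3, 271 and 265 without UV-C 1 d replicates 1 and 2, 1437 with DESeq2, and 1313, with 645 risers and 668 fallers, with group weights. At 3 d the count of 3093 was 1930 and 1864 without control replicates 1 and 2, 1716 without UV-C 3 d replicate 2, 3727 without UV-C 3 d replicate 3 and 1905 in a fit of these groups alone, and group weights gave 1493 risers and 1313 fallers. At 7 d the count of 1277 was 632, 559 and 818 without control replicates 1, 2 and 3, 681 without UV-C 7 d replicate 1, 2129 in a fit of these groups alone and 2323, with 1043 risers and 1280 fallers, with group weights. Fallers also outnumbered risers without control replicate 1 (333 and 299), 2 (315 and 244) or 3 (430 and 388) and without UV-C 7 d replicate 1 (342 and 339) or 3 (441 and 412).

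**Figure D3:**
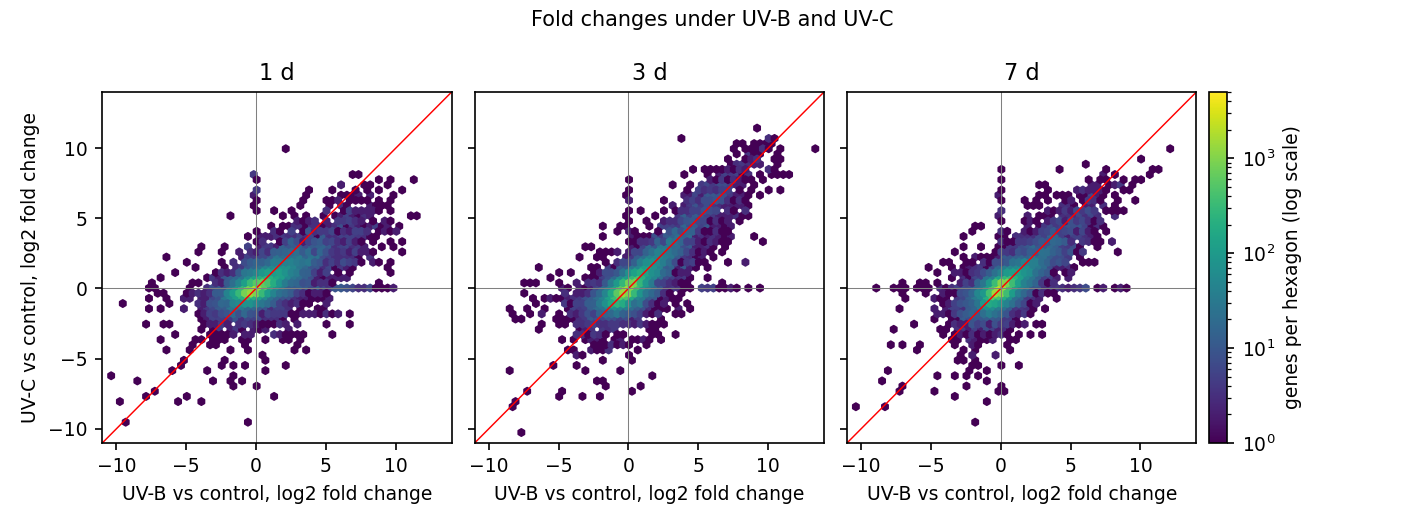
Log2 fold change against the control under UV-B (horizontal) and UV-C (vertical) at 1, 3 and 7 d, with shading for the number of genes per hexagon and a line where both are equal. Over the 18265 genes, Pearson's r was 0.68, 0.84 and 0.75, against 0.37, 0.35 and 0.43 in simulated unchanged groups with shared controls.

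Direct contrasts of UV-C with UV-B at equal duration showed differences between the treatments that do not involve the control. At 1 d, 1874 genes were higher under UV-C and 2036 lower, at 3 d 830 and 740, and at 7 d 595 and 516. Which direction held more genes depended on the processing. At 1 d it was 2095 higher and 1748 lower with upper quartile scaling, 1922 and 1918 with a filter of 1 CPM in 3 libraries, and 1229 and 995 or 1505 and 1353 without UV-C 1 d replicate 1 or 3. At 3 d it was 555 and 578 with no filter on low counts, 6 and 25 in a fit of these groups alone, 402 and 422 or 465 and 475 without UV-B 3 d replicate 2 or 3, and 682 and 722 without UV-C 3 d replicate 3. A minimum log2 fold change of 1 left 256 and 348 at 3 d and 223 and 290 at 7 d. Median log2 fold changes of the higher genes were 0.81, 0.73 and 0.76, and of the lower genes -1.09, -0.94 and -1.13. Differences of at least 8-fold were most frequent at 1 d, when 329 genes were that much lower under UV-C and 72 that much higher.

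Genes distinctive of UV-B were those called against the control under UV-B, not under UV-C, and different between the bands in the same sense. There were 1505 distinctive risers and 1407 distinctive fallers at 1 d, 306 and 485 at 3 d, and 227 and 309 at 7 d. Fallers outnumbered risers at 1 d with upper quartile scaling (1584 and 1284), with a filter of 1 CPM in 3 libraries (1452 and 1414), and without control replicate 3, UV-B 1 d replicate 2 or 3 or UV-C 1 d replicate 1 or 3 (1350 and 1276, 842 and 834, 1239 and 1142, 1035 and 814, 1106 and 923). Risers outnumbered fallers in fits of the groups compared alone at 3 d (11 and 3) and 7 d (305 and 303), and with a minimum log2 fold change of 1 at 3 d (146 and 137). The 1505 risers of 1 d took 7.22% ± 0.15 of counts in the control, 16.5% ± 2.3 under UV-B and 8.75% ± 0.73 under UV-C at that duration. At 3 d, whose contrasts were not used to choose them, they took 13.7% ± 1.9 under UV-B and 11.9% ± 2.7 under UV-C. The 1407 fallers of 1 d took 16.5% ± 0.17 in the control, 9.05% ± 0.62 under UV-B and 15.6% ± 0.88 under UV-C. The 227 risers of 7 d took 0.926% ± 0.04 in the control and 1.94% ± 0.22 under UV-B at 7 d, against 0.883% ± 0.055 under UV-C. At 1 d, whose contrasts were not used to choose them, they took 1.96% ± 0.027 under UV-B, against 1.03% ± 0.026 under UV-C.

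Genes distinctive of UV-C by the mirrored rule were fewer, with 73 risers and 65 fallers at 1 d, 124 and 184 at 3 d, and 101 and 99 at 7 d. Fallers outnumbered risers at 1 d without control replicate 1 or 2, UV-B 1 d replicate 1 or 3 or UV-C 1 d replicate 2 or 3 (27 and 16, 18 and 14, 58 and 55, 66 and 60, 35 and 31, 107 and 104). They did so at 7 d with upper quartile scaling (96 and 91), a minimum log2 fold change of 1 (34 and 26), and without control replicate 3 (67 and 58) or UV-B 7 d replicate 1 (82 and 76). The 73 risers of 1 d took 0.205% ± 0.0044 of counts in the control, 0.408% ± 0.033 under UV-C and 0.222% ± 0.0098 under UV-B. At 3 and 7 d of UV-C they took 0.304% ± 0.013 and 0.308% ± 0.0083, against 0.209% ± 0.0068 and 0.235% ± 0.012 under UV-B. The 65 fallers of 1 d took 0.455% ± 0.012 in the control, 0.301% ± 0.023 under UV-C and 0.499% ± 0.042 under UV-B. The 99 fallers of 7 d took 0.409% ± 0.011 in the control, 0.237% ± 0.01 under UV-C and 0.438% ± 0.019 under UV-B. At 1 and 3 d they took 0.359% ± 0.021 and 0.347% ± 0.023 under UV-C, against 0.565% ± 0.039 and 0.485% ± 0.018 under UV-B. Their median log2 fold change against the control was -0.26 and -0.4 there under UV-C, and -0.05 and 0.02 under UV-B. The higher shares under UV-B thus do not describe the typical gene. Shares at the duration of choice restate the choice, here and for the genes distinctive of UV-B.

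Of the contrasts of the bands, that at 3 d depended most on the fit. Its count of 1570 was 31 in a fit of the 6 libraries alone and 600 with group weights. It was 1034, 824 and 940 without UV-B 3 d replicates 1, 2 and 3, 933 without UV-C 3 d replicate 1 and 1404 without replicate 3. Simulated unchanged groups gave 14.8 calls on average. With simulated changes of 1.5, 2 and 4-fold, this contrast gave 46 false calls beside 5, 17 and 44 recovered genes. The contrast at 1 d gave 14 beside 0, 17 and 38. At both durations false calls were a larger share than the threshold allows. The contrast at 7 d gave 0 false calls beside 0, 16 and 41. These simulations do not give the false share among the 1570. The 1 d count of 3910 was 2326 without UV-B 1 d replicate 2, 2224 without UV-C 1 d replicate 1 and 1797 in a fit of these groups alone. The 7 d count of 1111 was 549 and 433 without UV-B 7 d replicates 2 and 3, 595, 471 and 524 without UV-C 7 d replicates 1, 2 and 3, 1717 with DESeq2 and 1911 with group weights.

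The distinctive counts moved in the same way. For UV-B, the 2912 genes of 1 d were 1676 without UV-B 1 d replicate 2, 1849 without UV-C 1 d replicate 1 and 1390 in a fit of these groups alone. The 791 of 3 d were 425 and 442 without UV-B 3 d replicates 2 and 3, 543 without UV-C 3 d replicate 3, 14 in a fit of these groups alone and 371 with group weights. The 536 of 7 d were 283 and 221 without UV-B 7 d replicates 2 and 3, 351, 282 and 291 without UV-C 7 d replicates 1, 2 and 3, and 912 with group weights. For UV-C, the 138 genes of 1 d were 43, 32 and 41 without control replicates 1, 2 and 3, 37, 66 and 211 without UV-C 1 d replicates 1, 2 and 3, 257 with DESeq2 and 87 in a fit of these groups alone. The 308 of 3 d were 193 and 188 without control replicates 1 and 2, 170 and 188 without UV-B 3 d replicates 1 and 2, 174, 91 and 481 without UV-C 3 d replicates 1, 2 and 3, 463 with DESeq2, 1 in a fit of these groups alone, and 108, of which 57 rose, with group weights. The 200 of 7 d were 96, 89 and 125 without control replicates 1, 2 and 3, 116 and 88 without UV-B 7 d replicates 2 and 3, 68, 78 and 80 without UV-C 7 d replicates 1, 2 and 3, 344 with DESeq2, 327 in a fit of these groups alone and 488 with group weights.

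Under UV-B, 1244 genes were higher at 7 d than at 1 d and 1521 lower, with median log2 changes of 0.78 and -1.14. Of the 3758 genes above the control at 1 d of UV-B, 1167 were called lower at 7 d than at 1 d and 29 higher. Of the 3160 below the control at 1 d, 728 were called higher at 7 d than at 1 d and 20 lower. Both contrasts hold the UV-B 1 d libraries, which favours opposite signs. Simulated unchanged groups gave at most 2 such genes, but averaged only 0.65 calls at 1 d, so they cannot measure this effect. The count of 2765 was 1014 without UV-B 1 d replicate 2, 1518 and 1209 without UV-B 7 d replicates 1 and 3, and 1401 in a fit of these groups alone.

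Under UV-C, 655 genes were higher at 7 d than at 1 d and 832 lower, with median log2 changes of 0.65 and -0.96. Of the 676 genes above the control at 1 d of UV-C, 133 were called lower at 7 d than at 1 d and 1 higher, and of the 409 below it, 78 were called higher and 5 lower. These overlaps share the UV-C 1 d libraries, which favours opposite signs. Simulated unchanged groups gave at most 3 such genes, but averaged only 1.8 calls at 1 d, so they cannot measure this effect. The count of 1487 was 325 and 894 without UV-C 1 d replicates 1 and 2, 504, 753 and 684 without UV-C 7 d replicates 1, 2 and 3, 2248 with DESeq2 and 950 in a fit of these groups alone.

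The changes from 1 d to 7 d had a common part that involves no shared library. No unirradiated library was taken at 1 d or 7 d, so a change with time alone cannot be told from it. Under both bands, 227 genes rose and 240 fell between 1 d and 7 d. Independent lists would share 45 and 69, and simulated unchanged groups, with few calls to share, shared 0. Changes in opposite directions were called for 33 genes. Over all tested genes, which are not independent replicates, the changes had Pearson's r of 0.37 and Spearman's rho of 0.34, with the same direction for 60.9%. This overlap was examined after the data were seen, and its count of 467 was 229 without UV-B 1 d replicate 2, 257 and 238 without UV-B 7 d replicates 1 and 3, 128 and 257 without UV-C 1 d replicates 1 and 2, 175, 259 and 192 without UV-C 7 d replicates 1, 2 and 3, 751 with DESeq2 and 205 in a fit of each band alone. Risers outnumbered fallers with group weights (241 and 215) and without UV-B 1 d replicate 1 (268 and 256), UV-B 7 d replicate 3 (125 and 113), UV-C 1 d replicate 2 (144 and 113) or UV-C 7 d replicate 2 (142 and 117).

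The change from 1 d to 7 d differed between the bands for 395 genes in the test of the interaction. For 206 of them the change was more positive under UV-C and for 189 more negative, and for 342 the fitted changes had opposite signs. Choosing genes by a difference of the changes favours opposite signs. Over all tested genes, 33 were called in both bands in opposite directions. The count was 161 and 163 without UV-B 1 d replicates 2 and 3, 132 and 51 without UV-B 7 d replicates 2 and 3, 54 without UV-C 1 d replicate 1, 87, 121 and 236 without UV-C 7 d replicates 1, 2 and 3, 215 with no filter on low counts, 1075 with DESeq2 and 39 in a fit of the 12 libraries alone. With upper quartile scaling it was 385, of which 153 were more positive under UV-C and 232 more negative. The negative side was also the larger with a filter of 1 CPM in 3 libraries (186 and 184), the replicate number as a block (165 and 158), a minimum log2 fold change of 1 (100 and 66), and without UV-B 1 d replicate 3 (92 and 71) or UV-B 7 d replicate 1 (220 and 163).

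Under all 6 treatments, 167 genes were higher than in the control and 88 lower. Independent lists would give 0.0237 and 0.00579, but the 6 comparisons share the same controls, so their lists are not independent. Simulated unchanged groups gave 0, with few calls to share, which does not measure what the shared controls add. The 167 risers took 0.319% ± 0.018 of counts in the control, 1.66% ± 0.28, 1.51% ± 0.31 and 1.08% ± 0.23 after 1, 3 and 7 d of UV-B, and 0.921% ± 0.18, 1.33% ± 0.49 and 0.736% ± 0.14 after 1, 3 and 7 d of UV-C. Their median log2 fold change, with genes absent from the control at their bound, ran from 2.23 in UV-C at 7 d to 3.16 in UV-B at 1 d. The 88 fallers took 1.18% ± 0.043 in the control, between 0.549% ± 0.034 and 0.723% ± 0.049 under UV-B, and between 0.663% ± 0.091 and 0.779% ± 0.033 under UV-C. The count of 255 was 98, 62 and 100 without control replicates 1, 2 and 3, 135 and 125 without UV-C 1 d replicates 1 and 2, 149 without UV-C 7 d replicate 1, and 367 without UV-C 3 d replicate 3. It was 466 with DESeq2, and with group weights 392, of which 144 rose and 248 fell, so the majority of risers holds under the other scalings and not in that fit.

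PITA_000045509-RA was the gene with the largest minimum rise among 123 eligible genes called higher under all 6 treatments. It had 2 counts over the 3 control libraries, or 0.0909 ± 0.0788 CPM (SD, n = 3), and at least 3 counts in each of the 18 irradiated libraries. Its level was 11.1 ± 7.17, 31.1 ± 13.3 and 11.8 ± 2.12 CPM after 1, 3 and 7 d of UV-B, which is 125 times (95% counting interval 34.3 to 1040), 349 times (96.4 to 2890) and 133 times (36.3 to 1100) the control. After 1, 3 and 7 d of UV-C it was 5.26 ± 4.22, 9.6 ± 7.89 and 4.29 ± 2.35 CPM, or 59.1 times (16 to 494), 105 times (28.8 to 876) and 49.1 times (13.2 to 411) the control. These exact binomial intervals cover counting error only. The adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 0.00028 in UV-B at 3 d and 0.028 in UV-C at 1 d. With group weights in limma the Benjamini-Hochberg adjusted p was 0.21, 0.094 and 0.11 in UV-C at 1, 3 and 7 d, so these calls were lost, with fitted log2 fold changes of 4.45, 5.35 and 4.81 in place of 5.63, 6.49 and 5.35. The call at 1 d of UV-C was also lost without control replicate 1, 2 or 3 or UV-C 1 d replicate 1 or 2 (Benjamini-Hochberg adjusted p of 0.092, 0.098, 0.11, 0.079 and 0.085 in edgeR, fitted log2 fold changes of 5.98, 5.96, 5.11, 5.29 and 5.21), and that at 7 d without control replicate 1, 2 or 3 or UV-C 7 d replicate 1 or 3 (0.069, 0.075, 0.077, 0.066 and 0.051, fitted log2 fold changes of 5.70, 5.69, 4.81, 5.05 and 5.16). Without UV-C 3 d replicate 2 the fitted log2 fold change at 3 d of UV-C was 5.79. Fits of only the groups compared gave no test of this gene at 1 and 3 d of UV-C, since the filter on low counts removed it there.

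PITA_000040947-RA was the gene with the largest minimum fall among 70 eligible genes called lower under all 6 treatments. It fell from 63.2 ± 20.3 CPM in the control to 11.3 ± 9.99, 7.01 ± 5.32 and 13.8 ± 3.65 CPM after 1, 3 and 7 d of UV-B, log2 fold changes of -2.49 (SE 0.73), -3.17 (SE 0.76) and -2.19 (SE 0.72). After 1, 3 and 7 d of UV-C it fell to 1.29 ± 0.43, 0.97 ± 0.429 and 2.26 ± 1.56 CPM, log2 fold changes of -5.60 (SE 0.89), -6.03 (SE 0.93) and -4.77 (SE 0.84). The log2 fold change was -3.72 with group weights and -3.17 without UV-B 1 d replicate 1 at 1 d of UV-B, -3.95 without UV-B 3 d replicate 3 at 3 d of UV-B, and -5.52 without UV-C 7 d replicate 1 at 7 d of UV-C. All 18 irradiated libraries held fewer counts than any control library, at most 133 against at least 350. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p lay between 0.00069 in UV-C at 3 d and 0.043 in UV-B at 7 d. The latter call was lost without control replicate 1, 2 or 3 (0.068, 0.14 and 0.071) or UV-B 7 d replicate 1, 2 or 3 (0.078, 0.1 and 0.13). The fitted log2 fold changes there were -2.36, -1.91, -2.29, -2.42, -2.19 and -2.02, against -2.19 with all libraries. The gene was lower under UV-C than under UV-B at 1 d (log2 fold change -3.12, SE 0.86, adjusted p = 0.017 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That call was lost without UV-B 1 d replicate 1 (log2 fold change -2.45, 0.067) or UV-C 1 d replicate 3 (-2.91, 0.062), in a fit of these groups alone (-3.11, 0.11) and with group weights in limma (-1.84, 0.44), where the second value is the Benjamini-Hochberg adjusted p. The edgeR test gave -2.87 (adjusted p = 0.059) at 3 d and -2.57 (adjusted p = 0.066) at 7 d after Benjamini-Hochberg adjustment. Both passed with no filter on low counts (Benjamini-Hochberg adjusted p = 0.014 each in edgeR) and with DESeq2 (0.0092 and 0.017), that at 3 d also without UV-B 3 d replicate 1 (0.05 after rounding) and that at 7 d in a fit of these groups alone (0.015).

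PITA_000083386-RA was the gene with the largest minimum excess of UV-C over UV-B among 139 eligible genes called at all 3 durations. Its level was 70.6 ± 26.7 CPM in the control, 0.367 ± 0.319, 0.223 ± 0.0803 and 0.136 ± 0.133 CPM after 1, 3 and 7 d of UV-B, and 41.4 ± 25.8, 23.2 ± 24.6 and 82.1 ± 32.2 CPM after 1, 3 and 7 d of UV-C. UV-C exceeded UV-B by a log2 fold change of 6.72 (SE 1.04) at 1 d and 6.59 (SE 1.12) at 3 d, with adjusted p of 0.00046 and 0.0021 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At 7 d UV-B libraries held 3 counts in all, 2 of them in replicate 2, and the UV-C level was 603 times as high (95% counting interval 206 to 2930, adjusted p = 0.00054 by the same edgeR test with Benjamini-Hochberg adjustment). Every UV-C library held at least 14 counts and no UV-B library more than 4. Against the control, the log2 fold change was -7.49 (SE 1.05) and -8.21 (SE 1.11) at 1 and 3 d of UV-B. Under UV-C it was -0.77 (SE 0.67), -1.62 (SE 0.69) and 0.22 (SE 0.66), with Benjamini-Hochberg adjusted p of 0.52, 0.091 and 0.87 in edgeR. With group weights in limma the Benjamini-Hochberg adjusted p of the contrast of the bands was 0.16, 0.36 and 0.084 at 1, 3 and 7 d, although the log2 fold changes were 6.82, 5.32 and 8.86. That at 3 d was 0.093 in an edgeR fit of these groups alone, and the log2 fold change at 3 d was 5.35 without UV-C 3 d replicate 1. With group weights the falls against the control at 1 and 7 d of UV-B missed the threshold (0.061 and 0.051). The fall against the control at 3 d of UV-C passed the test with no filter on low counts (log2 fold change -1.63, Benjamini-Hochberg adjusted p = 0.033 in edgeR), with group weights in limma (-2.58, 0.025) and without UV-C 3 d replicate 1 (-2.87, 0.014), so whether UV-C lowers this gene at 3 d is open.

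PITA_000085805-RA was the gene with the largest minimum deficit of UV-C against UV-B among 134 eligible genes called at all 3 durations. It stood at 46 ± 1.78 CPM in the control, 33 ± 22.8, 52.8 ± 31.7 and 49.1 ± 8.41 CPM after 1, 3 and 7 d of UV-B, and 0.0449 ± 0.0778, 0.241 ± 0.0999 and 0.279 ± 0.257 CPM after 1, 3 and 7 d of UV-C. At 1 d the UV-C libraries held 1 count in all, in replicate 1, and the UV-B level was 771 times as high (95% counting interval 138 to 30500, adjusted p = 1.7e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). At 3 and 7 d the log2 fold change of UV-C against UV-B was -7.71 (SE 0.76) and -7.42 (SE 0.74), with adjusted p of 1.8e-05 and 5.6e-05 by the same edgeR test with Benjamini-Hochberg adjustment. No UV-C library held more than 4 counts and no UV-B library fewer than 58. Against the control, UV-B gave log2 fold changes of -0.48 (SE 0.46), 0.20 (SE 0.46) and 0.09 (SE 0.46) at 1, 3 and 7 d, none of which passed the test (adjusted p of 0.44, 0.77 and 0.91 in edgeR with Benjamini-Hochberg adjustment). With group weights in limma the Benjamini-Hochberg adjusted p of the contrast of the bands was 0.068 at 1 d and 0.12 at 3 d. The log2 fold change of UV-C against UV-B was -7.10 at 3 d without UV-B 3 d replicate 3 and -8.37 at 7 d without UV-C 7 d replicate 2.

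**Figure D4:**
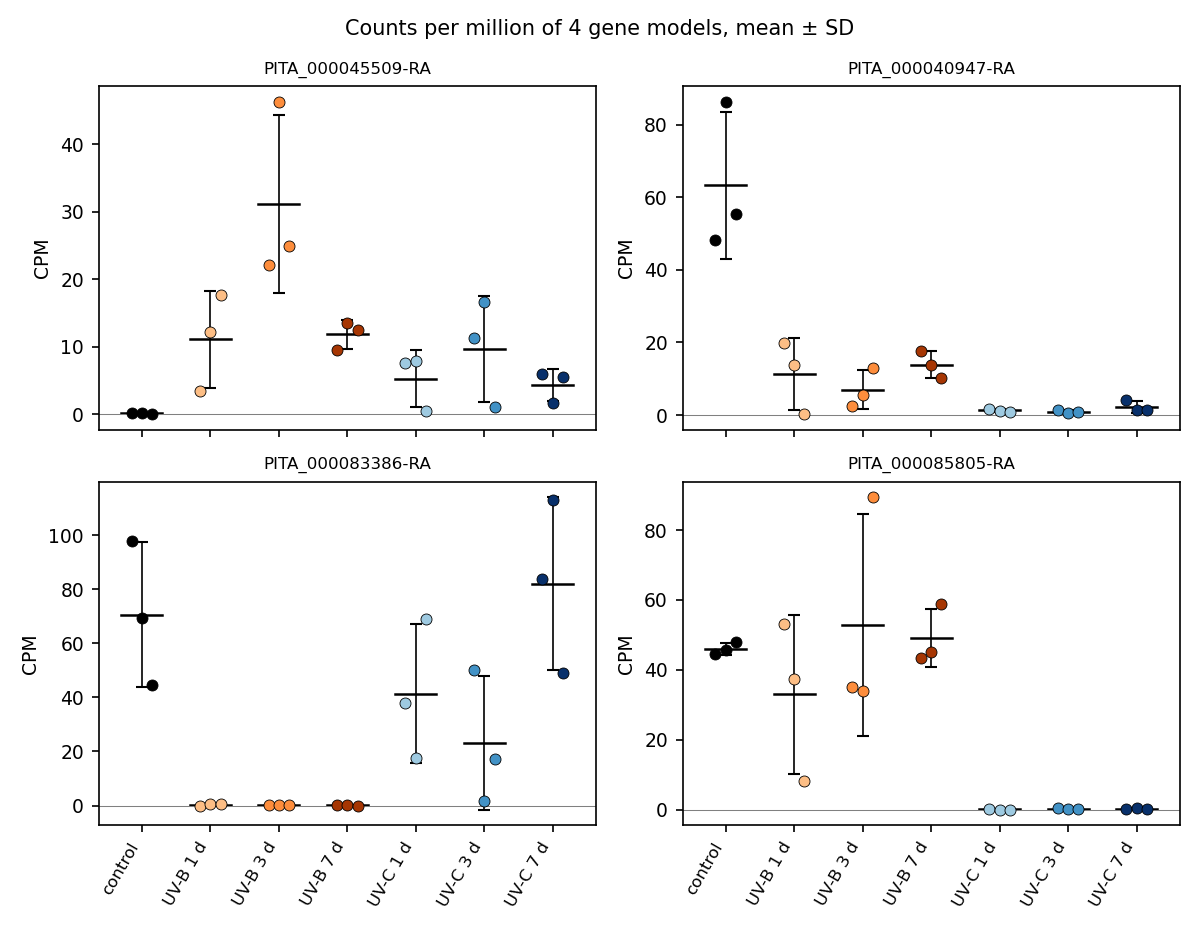
CPM of the 4 followed gene models in each of the 21 libraries (points), with the mean and SD of each group of 3. PITA_000083386-RA lies near 0 in the UV-B groups (at most 0.367 CPM on average) and PITA_000085805-RA in the UV-C groups (at most 0.279 CPM on average).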

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

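The response sizes corrected for noise, and the tests of a swap, of a wrong label and of a smaller response for UV-C 3 d replicate 3, were chosen only after the result was seen. The thinning of libraries and the other splits of the libraries were set out beforehand.

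Effects of the bands were tested against each other, and several differed. The change from 1 d to 7 d differed between UV-B and UV-C for 395 genes by the interaction test. The effect against the control differed between the bands for 3910 genes at 1 d, 1570 at 3 d and 1111 at 7 d, as the direct contrast of UV-C with UV-B measures it. PITA_000040947-RA, which fell under all 6 treatments, was lower under UV-C than under UV-B at 1 d, with a log2 fold change of -3.12. PITA_000083386-RA was higher under UV-C by fitted log2 fold changes of 6.72, 6.59 and 9.07 at 1, 3 and 7 d, of which the last rests on 3 counts in UV-B. PITA_000085805-RA was lower under UV-C by fitted log2 fold changes of -9.11, -7.71 and -7.42, of which the first rests on 1 count in UV-C. The last pair of genes was chosen for its difference between the bands, so these folds restate the choice.

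For each contrast of 2 groups there are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split was the 1 of 10 with the most genes in each of the 11 contrasts. Against the control the real and highest other counts were 6918 and 1, 5955 and 0, and 3365 and 0 for UV-B at 1, 3 and 7 d, and 1085, 4708 and 2283 with 0 in each other split for UV-C. For UV-C against UV-B they were 3910 and 2, 1570 and 106, and 1111 and 0 at 1, 3 and 7 d, and for 7 d against 1 d they were 2765 and 1 under UV-B and 1487 and 0 under UV-C. For the interaction, 8 of 10 splits of the 7 d libraries gave at least the real 395 genes, the highest 1188. Those splits mix the bands at 7 d and keep them apart at 1 d, so they measure the band difference of 1 d, a structure of the samples, and say nothing on chance.

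For the sets built from several contrasts, 100 splits were compared, and under 0.05 of them reached the real count. This excludes a random assignment of the libraries to groups and no more: nearly all splits mix groups that differ, so it does not show how many of the genes are real. For genes common to the bands, 2 of 100 splits reached the real count at 1 d (real 809, highest other 3163) and 1 of 100 at 3 d (3093 and 3004) and 7 d (1277 and 1114). For genes distinctive of UV-B it was 1 at 1 d (2912 and 1085), 3 at 3 d (791 and 2938) and 3 at 7 d (536 and 1179), and for UV-C 1 at each duration (138 and 4, 308 and 292, 200 and 21). The splits with several times the real count kept a whole group together, UV-B at 1 d in the first case and the controls at 3 d and 7 d, and so point to that structure of the samples. For genes changed at all durations it was 1 of 100 for UV-B (2268 and 1), UV-C (392 and 1) and both bands (255 and 0), and also 1 of 100 for the common change from 1 d to 7 d (467 and 0).

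At 1 d, 6.38 times as many genes were called against the control under UV-B as under UV-C. The size of this ratio is uncertain: it was 3.71 with DESeq2, 3.83 with group weights and 4.04 in fits of the groups compared alone, and 18.2, 24.4 and 18.7 without control replicates 1, 2 and 3 and 20.6 and 19.7 without UV-C 1 d replicates 1 and 2. Without UV-C 1 d replicate 3 it was 4.65. Each of these fits leaves 2 libraries in a group, so the rise without any control may reflect lower power. After every library had been thinned to the smallest total of 6177212 counts, the ratio was 6.41, with 6592 and 1028 genes, which argues against library size. The squared size of the response per gene, corrected for noise, was 3.13 times as large under UV-B, and at least 2.12 times on leaving out any of 9 libraries, which argues against unequal spread between replicates as the whole cause. A larger response to UV-B as given at 1 d is a candidate explanation, which cannot be assigned to wavelength, since the intensities were 280 and 28 µW/cm2.

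UV-C 3 d replicate 3 had a mean correlation of 0.902 with its mates, against 0.96 between them. Thinning changed that mean by -0.0025, and 0 libraries outside the group correlated better with replicates 1 and 2 than with their own group, which argues against depth and against a swap with another of the 21 libraries. A single wrong label stays open: the library's mean correlation with the UV-C 1 d libraries was 0.946, above their lowest pair of 0.931, and with UV-C 7 d it was 0.962 against 0.961. A smaller extent of the same response also stays open, since its difference from its mates had a cosine of -0.55 with the change from the control to UV-B at 3 d. The library may hold either, and without it the UV-C 3 d count against the control was 5858 in place of 4708.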

How the results depend on the processing

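All choices below were set out before the data were examined, except the group weights and the results on genes changed in the same direction from 1 d to 7 d in both bands. DESeq2 size factors, upper quartile factors and the filter of 1 CPM in 3 libraries left all 25 counts of genes within 1.5 times their reported value. With no filter on low counts, 24 of 25 did so and the interaction gave 215 genes. Of the values that the alternatives gave for the followed genes, 419 kept their side of the threshold, 32 lost it and 9 gained it. A gene that the filter of an alternative removed gave no value and is not in this tally. This befell PITA_000045509-RA in fits of only the groups compared at 1 and 3 d of UV-C, so the losses are understated. Without 1 library, 4 values changed sign, none of them called: PITA_000083386-RA at 7 d of UV-C (0.22 to -0.04 and -0.09) and PITA_000085805-RA at 3 d (0.20 to -0.42) and 7 d (0.09 to -0.07) of UV-B. The gene list tests (camera with a preset and an estimated correlation, and fry) were not run, since identifiers carry no names here. Depth limits low genes most.

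Replicate numbers do not pair these libraries. The mean correlation of deviations of same-numbered libraries was -0.006 (range -0.368 to 0.365, over 0.1 in 10 of 63 pairs), 4 of 21 libraries correlated best with their own number, and over the 500 most variable genes the mean was -0.024. With the replicate number as a block, all 25 counts stayed within 1.5 times (for example 6799 for UV-B at 1 d, 1025 for UV-C at 1 d and 323 for the interaction).

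A minimum log2 fold change of 1 lowered 24 of 25 counts by more than 1.5 times, by its construction: 3760, 3232 and 1796 for UV-B at 1, 3 and 7 d; 703, 2520 and 1022 for UV-C; 1778, 604 and 513 for UV-C against UV-B; 1261 and 578 for 7 d against 1 d of UV-B and UV-C; 166 for the interaction. It left 520, 1707 and 607 genes common to the bands, 1245, 283 and 259 distinctive of UV-B, 73, 90 and 60 distinctive of UV-C, 1166 and 249 changed at all durations of UV-B and UV-C, and 217 with a common change from 1 d to 7 d.

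DESeq2 raised all 25 counts, 11 of them by over 1.5 times: 1966 for UV-C at 1 d, 1717 for UV-C against UV-B at 7 d, 2248 for 7 d against 1 d of UV-C, 1075 for the interaction, 1437 common at 1 d, 257, 463 and 344 distinctive of UV-C, 713 at all durations of UV-C, 466 at all durations of both bands and 751 with a common change from 1 d to 7 d. Limma voom with group weights moved 13 by over 1.5 times: 5060 for UV-B at 7 d, 1873 and 4353 for UV-C at 1 and 7 d, 600 and 1911 for UV-C against UV-B at 3 and 7 d, 1313 and 2323 common at 1 and 7 d, 371 and 912 distinctive of UV-B at 3 and 7 d, 108 and 488 distinctive of UV-C at 3 and 7 d, 637 at all durations of UV-C and 392 of both bands. A fit of only the groups compared moved 15 by over 1.5 times: 2711 and 4194 for UV-C at 3 and 7 d, 1797 and 31 for UV-C against UV-B at 1 and 3 d, 1401 and 950 for 7 d against 1 d of UV-B and UV-C, 39 for the interaction, 1905 and 2129 common at 3 and 7 d, 1390 and 14 distinctive of UV-B at 1 and 3 d, 87, 1 and 327 distinctive of UV-C, and 205 with a common change from 1 d to 7 d. For these 3 alternatives the cause was not tested.

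Leaving out each library in turn gave these ranges, and the libraries that move a count by over 1.5 times stand beside it in the report. The group concerned then holds 2 libraries, so a lower count may reflect lower power. Against the control: 5191 to 6510, 4211 to 5991 and 1933 to 2610 for UV-B, and 220 to 1520, 2168 to 5858 and 965 to 1658 for UV-C. UV-C against UV-B: 2224 to 3538, 824 to 1404 and 433 to 825. The 7 d against 1 d contrasts: 1014 to 3000 for UV-B and 325 to 1622 for UV-C, with 51 to 541 for the interaction and 128 to 542 for the common change. Common to the bands: 182 to 1075, 1716 to 3727 and 559 to 1078. Distinctive of UV-B: 1676 to 2686, 425 to 847 and 221 to 414, and of UV-C 32 to 211, 91 to 481 and 68 to 158. Changed at all durations: 1317 to 2196 for UV-B, 81 to 524 for UV-C and 62 to 367 for both bands. For 14 of 25 counts, leaving out some library raised the count.

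Whether higher or lower calls were the more numerous also depended on these choices. That order turned in 6 of 25 counts with upper quartile factors, 4 with the filter of 1 CPM, 1 with no filter, 1 with the block, 5 with a minimum log2 fold change of 1, 4 in fits of only the groups compared, 8 with group weights, and 0 with DESeq2 or its size factors. Over all alternatives and left-out libraries it turned in 18 counts. In 7 it never did: UV-B at 1 and 7 d and UV-C at 1 and 3 d against the control, 7 d against 1 d in each band, and genes common to the bands at 3 d.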

Other observations

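All measures in this part were chosen after the data were seen. A small set of genes was nearly silent in the control libraries and present in every irradiated library. These 17 genes lay below 1 CPM in all control libraries and at or above 1 CPM in all 18 irradiated ones. Each had a median of at least 5 CPM in the irradiated libraries. The reverse held for 3 genes, and their identifiers are not printed under the limit of 4 gene models. Among all 1330 sets of 3 of the 21 libraries, 1 set, the controls, gave as many as 17 such genes, and the highest other gave 3. Nearly all of these sets mix groups and the measure was chosen after the pattern was seen, so this count does not test chance. No unirradiated library was taken later than the control, so a change with time alone would give the same pattern.

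The responses to the treatments can be compared by size and direction from products of differences that share no library. This removes the sampling noise of single control libraries. All products still use the 0 h control, so a difference with time common to the treatments stays in every size and cosine. The squared size per gene (log2 scale) was 1.33 (range over leaving out each library 1.1 to 1.48), 1.28 (1.1 to 1.62) and 0.8 (0.74 to 0.85) for UV-B at 1, 3 and 7 d, and 0.43 (0.28 to 0.63), 0.89 (0.52 to 1.55) and 0.54 (0.48 to 0.67) for UV-C. The cosine between UV-B and UV-C was 0.76 (0.69 to 0.9) at 1 d, 0.93 (0.87 to 1.08) at 3 d and 0.79 (0.76 to 0.82) at 7 d, where values above 1 arise from the correction for noise. Within UV-B it was 0.92 (0.9 to 0.94) between 1 d and 3 d, 0.95 (0.87 to 0.99) between 3 d and 7 d and 0.8 (0.72 to 0.85) between 1 d and 7 d. Within UV-C the same pairs gave 0.8 (0.7 to 0.97), 0.88 (0.76 to 1.04) and 0.69 (0.63 to 0.87). The lowest of the 15 cosines were 0.58 (0.55 to 0.62) between UV-B at 1 d and UV-C at 7 d, 0.59 (0.54 to 0.74) between UV-B at 7 d and UV-C at 1 d, and 0.63 (0.56 to 0.77) between UV-B at 3 d and UV-C at 1 d, whose ranges overlap.

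Placed on the axis from the control mean at 0 to the UV-B 3 d mean at 1, the libraries of UV-C at 3 d lay at 0.79, 1 and 0.39, those of UV-C at 1 d at 0.37, 0.48 and 0.24, and those of UV-C at 7 d at 0.53, 0.35 and 0.54. The UV-B 7 d libraries lay at 0.63, 0.79 and 0.7.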
